A study of Homo sapiens with 8 samples.

How the data were processed

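RNA from P-body preparations and from the cytosolic fraction of 2 human acute myeloid leukaemia cell lines was sequenced. HEL is an erythroleukaemia line and MOLM-13 is a line of monocytic character. The titles of the 8 libraries give 4 groups of 2, namely HEL P-body, HEL cytosol, MOLM-13 P-body and MOLM-13 cytosol. The word "cyto" in the titles was read as cytosolic. How the P-bodies were isolated is not given in the sources used here. Per the labels, total RNA was extracted with a miRNeasy Micro kit and libraries were made with a NEBNext Ultra II kit. Nothing in the labels says that replicates came from separate cultures, so each p-value measures only the spread between these libraries, which may be technical.

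The deposited values are raw read counts per gene symbol, in a table for each line, and are whole numbers with a different total in each library. The submitters' processing notes name STAR, SAMtools 1.12, DESeq2 and the build GRCh38. The read counter, the annotation release, the strand setting and any filter are not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart, and members of families with near-identical copies, such as ribosomal protein genes with their pseudogenes, replication-dependent histones and KRAB zinc finger genes, may share reads.

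Each table had 61544 rows. A set of 112 symbols stood on 1348 rows and was left out of the tests, because a symbol did not name a single gene there. These rows held 0.0193% to 0.0264% of counts in the HEL libraries and 0.0381% to 0.0477% in the MOLM-13 libraries. The remaining 60196 symbols were used, of which 56936 were matched to GENCODE release 29 on GRCh38, directly or through older symbols. Transcript length and GC content were taken from the transcript with the longest coding sequence, and gene coordinates are gene spans in that annotation. In each line 273 tested genes had no match and stayed out of the analyses of transcript properties.

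Total counts ran from 13153551 to 18071473 per HEL library and from 5897625 to 11000536 per MOLM-13 library. Both replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom of 6.15, 4.55, 1.88 and 1.87 for HEL P-body, HEL cytosol, MOLM-13 P-body and MOLM-13 cytosol over genes with at least 20 counts summed over the pair. This shows only that the libraries of a pair are not copies of each other, and not that they are independent samples. The libraries were counted as separate samples because the labels list them so. The common biological coefficient of variation was 0.0781 in HEL and 0.0382 in MOLM-13.

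P-body and cytosolic libraries were compared within each line with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test on counts with TMM size factors, after filterByExpr with its smallest count of 10. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p below 0.05 were called. The TMM factors were 0.884 to 0.903 in HEL P-body libraries and 1.12 in HEL cytosolic libraries, and 0.858 to 0.860 against 1.16 to 1.17 in MOLM-13. Scaling by library totals in place of TMM moved the median log2 change by -0.33 in HEL and by -0.44 in MOLM-13. There was no spike-in in the counts used here, so each change is relative to the bulk of genes in the same library and is not a change in the amount of RNA. The difference between lines was the interaction term, MOLM-13 minus HEL, in a quasi-likelihood fit of all 8 libraries. This fit shares its estimate of each gene's spread between the lines, although HEL libraries varied more than MOLM-13 libraries.

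A set of 22 gene lists was tested within each line with camera in limma 3.58.1, with a preset correlation of 0.01, again with an estimated correlation, and with fry, for lists with at least 5 tested members. The same test on the difference between lines was added after the data had been examined. With an estimated correlation camera uses the residual degrees of freedom of the fit, which were 2 in each line. A call can therefore be lost there without correlation between the members of a list. The lists were cytosolic ribosomal proteins, translation factors, mitochondrially encoded mRNAs, nuclear-encoded respiratory chain subunits, glycolytic enzymes, proteasome subunits, replication-dependent histones, myeloid tumour suppressors, P-body and mRNA decay proteins, chromatin regulators, KRAB zinc finger proteins, ubiquitin ligases and adaptors, centrosome and spindle proteins, endoplasmic reticulum chaperones and translocon, nuclear-retained long noncoding RNAs, small structured noncoding RNAs, immediate-early and short-lived mRNAs, iron handling and ferritinophagy, autophagy, and markers of erythroid and megakaryocytic, monocytic and granulocytic, and lymphoid cells.

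The groups, tests, lists and most alternatives were chosen before the data were examined. Named genes followed a rule fixed at the same time. They were the 5 genes with the greatest change in each line and direction among called protein-coding genes with a mean of at least 10 CPM (counts scaled to a common library size) and separated libraries, the member of each list with the lowest p-value in each line, 10 genes fixed by name, of which 1 is not reported here, and the 5 genes per direction with the lowest p-value for the difference between lines. By the rule a list member is given in both lines, but below most are given only in the line that selected them. Such a value does not show the change in the other line. The alternatives were DESeq2 1.42.0, RLE size factors, library totals, other filters on low counts, a minimum change of 2-fold tested by glmTreat, the replicate number as a block, a joint fit of both lines, each library left out in turn, and mitochondrial, small noncoding and histone genes left out. Offsets that remove each library's trend on GC content and transcript length, and TMM with each library as the reference, were added after the data had been examined. Under these offsets camera ran without the precision weights used in the other list tests, and genes with no match in the annotation were left out. A list call lost, kept or gained under the offsets can therefore not be put down to the trend alone.

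The tests were checked on simulated counts with the means and library sizes of these data. In the HEL comparison, run on 14484 genes, 72.9% of genes changed 2-fold and 95.8% of genes changed 4-fold were recovered, and 0.0910% of unchanged genes were called. In the MOLM-13 comparison, run on 13716 genes, 89.4% and 96.0% were recovered, and 0.0444% of unchanged genes were called. For the difference between lines, run on 16954 genes, recovery was 56.2% at 2-fold and 62.0% at 4-fold. Only a small part of the simulated genes was changed, in random directions and with no trend on GC content. In the real data 54.6% of tested genes were called in HEL and 60.8% in MOLM-13. The simulation therefore does not test the scaling, or the rate of false calls, where most genes change. Shares of counts are given per library without a test, since an exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333.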

Results

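P-bodies are cytoplasmic granules of RNA and protein in which messenger RNAs are held outside active translation. The study asked which RNAs sit in P-bodies of myeloid leukaemia cells, and the RNA content of P-bodies was compared with that of the cytosolic fraction in HEL and in MOLM-13. Each line had 2 P-body and 2 cytosolic libraries. The HEL P-body libraries held 18071473 and 17058567 counts and the HEL cytosolic libraries 13153551 and 15569634. The MOLM-13 P-body libraries held 11000536 and 9868469 counts and the cytosolic libraries 5897625 and 7098927.

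In HEL, most tested mRNAs of KRAB zinc finger proteins (70 of 100) and ubiquitin ligases (42 of 67) were higher in P-bodies, and most mitochondrially encoded mRNAs (13 of 13), glycolytic enzymes (14 of 17) and erythroid and megakaryocytic markers (18 of 28) were lower. The camera test called these lists with its preset correlation, and the adjusted p was 0.762 for each with an estimated correlation. The greatest rises among named genes were those of LIMCH1, an actin-associated protein (11.3-fold, from 4.57 ± 0.71 to 52.0 ± 0.44 CPM, SD, n = 2), RGS17, a regulator of G protein signalling (9.39-fold), CFAP210, a cilium-associated protein (9.02-fold), ZNF141, a KRAB zinc finger protein (8.98-fold), and FAM111B, a protease (7.84-fold). The lowest were ADRA2A, an adrenergic receptor (5.34-fold lower, from 28.2 ± 10.7 to 5.31 ± 2.98 CPM, SD, n = 2, and a log2 change of -3.06 without HEL P-body replicate 2 in place of -2.42), the integrin subunit ITGB5 (4.50-fold lower), the selenoprotein SELENON (4.49-fold lower), the aminopeptidase-like RNPEPL1 (4.44-fold lower) and UPF1, the helicase of nonsense-mediated decay (4.18-fold lower). Of 14772 genes tested, 4061 were higher and 4006 lower in P-bodies, and the change was at least 2-fold for 1855 and 937 of them (edgeR quasi-likelihood test, adjusted p below 0.05). Scaled by library totals, 2762 were higher and 6761 lower.

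Of 100 tested KRAB zinc finger genes, a family of transcriptional repressors, 70 were higher and 6 lower in HEL P-bodies, with a median log2 change of 1.13 (71 and 7 adjusted over the list alone). ZNF92 was 5.06-fold higher (log2 change 2.34 ± 0.085, SE) and ZNF267 3.58-fold higher. Ubiquitin ligases and adaptors had 42 of 67 members higher and 16 lower (the same counts adjusted over the list alone), with a median of 0.47. Among them KLHL28, a substrate adaptor, was 5.94-fold higher and MDM2, the ligase of p53, 2.14-fold higher. Of 58 centrosome and spindle genes, 31 were higher and 16 lower, over the list alone as well, with a median of 0.42, and CEP97, which restrains cilium assembly, was 4.76-fold higher. The camera adjusted p was 5.1e-13, 0.00112 and 0.00184 for these lists in that order, and the adjusted p was 0.762 for each with an estimated correlation.

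Each of the 13 mitochondrially encoded mRNAs was lower in HEL P-bodies, with a median log2 change of -0.81, and MT-ND4, a subunit of respiratory complex I, was 2.50-fold lower (228 ± 1.16 against 570 ± 64.7 CPM, SD, n = 2). Of 17 glycolytic enzymes, 14 were lower and 0 higher (15 and 0 adjusted over the list alone), with a median of -0.54, and the aldolase ALDOC was 2.41-fold lower. Erythroid and megakaryocytic markers, which mark the lineage of this line, had 18 of 28 members lower and 3 higher, over the list alone too, with a median of -0.45, and the platelet integrin ITGB3 was 3.73-fold lower. Of 42 immediate-early and short-lived mRNAs, 21 were lower and 7 higher (22 and 7 adjusted over the list alone), with a median of -0.35. The kinase PIM1 was 2.26-fold lower and the AP-1 subunit JUND 2.67-fold lower. The camera adjusted p was 8.8e-07, 8.2e-06, 0.000321 and 0.0195 in that order, and the adjusted p was 0.762 for each with an estimated correlation. With the trend on GC content and length removed, chosen after seeing the data, the calls of erythroid and megakaryocytic markers (median -0.073), immediate-early mRNAs (-0.043), centrosome and spindle genes (0.11) and ubiquitin ligases (-0.012) were lost. Under the same setting the medians were 0.63 for KRAB zinc finger genes and -0.18 for glycolytic enzymes, both still called, and ribosomal proteins were called higher (0.27). That setting also ran the list test without precision weights, so these changes in list calls may not come from the trend alone.

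The other lists tested in HEL were not called against the remaining genes. Cytosolic ribosomal proteins had 14 of 78 members higher and 2 lower, with a median of 0.12 that fell to -0.20 under library totals (camera adjusted p = 0.153). Translation factors had 14 of 36 higher and 8 lower, with EIF1AX, a start-site selection factor, 3.71-fold higher. Nuclear-encoded respiratory chain subunits had 6 of 70 higher and 15 lower, with SDHD 1.61-fold lower, and were called lower under library totals (median -0.38, camera adjusted p = 0.00229). Of 31 proteasome subunits, 11 were higher and 4 lower, and PSMC6 was 2.28-fold higher. Of 48 myeloid tumour suppressors, 22 were higher and 12 lower, and PHF6, a chromatin-associated protein mutated in leukaemia, was 3.69-fold higher. P-body and mRNA decay proteins had 16 of 44 higher and 11 lower, and TNRC6A, a partner of Argonaute, was 4.29-fold higher. Chromatin regulators had 26 of 62 higher and 21 lower, with the methyltransferase ASH1L 3.92-fold higher. Replication-dependent histones had 10 of 43 higher and 6 lower, and H2BC12 was 2.00-fold lower. Of 40 genes of endoplasmic reticulum chaperones and translocon, 15 were higher and 14 lower, with SEC62 higher by a log2 change of 1.59. Autophagy genes had 14 of 40 higher and 16 lower, with ATG4C 3.61-fold higher. Iron handling and ferritinophagy genes had 12 of 25 higher and 6 lower, with the autophagy receptor TAX1BP1 2.99-fold higher. Nuclear-retained long noncoding RNAs had 2 of 11 higher and 3 lower, with SNHG14 4.14-fold higher. Of 8 monocytic and granulocytic markers, 1 was higher and 2 lower, with the transcription factor SPI1 1.89-fold lower, and of 7 lymphoid markers 1 was higher and 3 lower, with CD4 1.97-fold lower. With 2 tested members, small structured noncoding RNAs were not tested as a list, and RN7SL1, the RNA of the signal recognition particle, was 1.54-fold higher, a call lost under library totals (log2 change 0.30). Adjusted over the list alone, the higher and lower counts were 10 and 1 for ribosomal proteins, 5 and 14 for respiratory chain subunits, 11 and 3 for proteasome subunits, 6 and 6 for histones, 15 and 16 for autophagy genes and 1 and 5 for lymphoid markers, and the same as over all genes for the other lists not called. Without HEL P-body replicate 2 myeloid tumour suppressors (median 0.22), chromatin regulators (0.17) and translation factors (0.11) were called higher. The first of these and chromatin regulators were also called without HEL P-body replicate 1 (0.14 and 0.042) and without HEL cytosol replicate 2 (0.20 and 0.10).

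In MOLM-13, most tested mRNAs of centrosomal proteins (48 of 59), KRAB zinc finger proteins (66 of 86) and ubiquitin ligases (43 of 67) were higher in P-bodies, and most ribosomal protein mRNAs (74 of 78) and mitochondrially encoded mRNAs (13 of 13) were lower. The camera test called these lists with its preset correlation, and the adjusted p was 0.270 for KRAB zinc finger proteins and 0.376 for the others with an estimated correlation. The greatest rises among named genes were those of UBLCP1, a phosphatase of the proteasome (5.50-fold, log2 change 2.46 ± 0.076, SE, n = 2), the zinc finger protein ZNF766 (5.41-fold), the membrane adaptor GAPT (5.17-fold), the Toll-like receptor TLR1 (5.15-fold) and BORA, an activator of Aurora A kinase (5.11-fold). The lowest were PLPPR3 (3.62-fold lower, from 39.3 ± 9.81 to 10.9 ± 5.21 CPM, SD, n = 2), BBLN (3.42-fold lower), ZNF787 (3.38-fold lower), FBRSL1 (3.29-fold lower) and the transcriptional coactivator CITED4 (3.21-fold lower). With the trend on GC content and length removed, chosen after seeing the data, the log2 changes of these 5 were -0.85, -0.55, -0.78, -0.82 and -0.43, all still called. Of 14089 genes tested, 4558 were higher and 4015 lower, and the change was at least 2-fold for 2150 and 927 of them (edgeR quasi-likelihood test, adjusted p below 0.05). Scaled by library totals, 2903 were higher and 7154 lower, so that the share of higher genes among those called was 28.9% in place of 53.2%, and DESeq2 called 2623 lower.

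Of 59 centrosome and spindle genes, 48 were higher and 6 lower in MOLM-13 P-bodies (the same adjusted over the list alone), with a median log2 change of 1.24, and CNTRL, a protein of the mother centriole, was 3.54-fold higher (log2 change 1.82 ± 0.044, SE). Of 86 KRAB zinc finger genes, 66 were higher and 4 lower (70 and 4 adjusted over the list alone), with a median of 1.15, and ZNF267 was 4.29-fold higher. Ubiquitin ligases and adaptors had 43 of 67 higher and 8 lower, over the list alone too, with a median of 0.81, and MDM2 was 3.07-fold higher. Their camera adjusted p was 7.4e-13, 9.4e-10 and 7.2e-07 in that order, and with an estimated correlation the adjusted p was 0.376, 0.270 and 0.376. Myeloid tumour suppressors had 25 of 50 higher and 14 lower (25 and 15 adjusted over the list alone), with the cohesin subunit SMC3 3.64-fold higher and a median of 0.24. Chromatin regulators had 33 of 62 higher and 20 lower (34 and 22 adjusted over the list alone), with ARID4A 3.58-fold higher and a median of 0.36. Autophagy genes had 21 of 40 higher and 7 lower, over the list alone as well, with TAX1BP1 3.73-fold higher and a median of 0.23. These last 3 lists passed narrowly, with camera adjusted p of 0.0183, 0.0492 and 0.0453 and an adjusted p of 0.376 for each with an estimated correlation. Under library totals their medians were -0.20, -0.08 and -0.21, with adjusted p of 0.0990, 0.107 and 0.105, and with CPM of at least 5 the adjusted p was 0.101, 0.174 and 0.101. The call of chromatin regulators was also lost under RLE (median 0.37, camera adjusted p = 0.0521), and that of tumour suppressors with the trend on GC content and length removed, chosen after seeing the data (median 0.13, camera adjusted p = 0.126). That setting left medians of 0.68 for centrosome and spindle genes, 0.69 for KRAB zinc finger genes and 0.39 for ubiquitin ligases, all still called.

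Of 78 cytosolic ribosomal protein genes, 74 were lower and 0 higher in MOLM-13 P-bodies (75 and 0 adjusted over the list alone), with a median log2 change of -0.50, and RPS2 was 1.73-fold lower (1229 ± 40.3 against 2130 ± 87.0 CPM, SD, n = 2). Each of the 13 mitochondrially encoded mRNAs was lower, with a median of -0.75, and MT-CO2, a subunit of cytochrome c oxidase, was 1.73-fold lower. Nuclear-encoded respiratory chain subunits had 43 of 71 lower and 10 higher (45 and 10 adjusted over the list alone), with a median of -0.27, although the member with the lowest p-value, NDUFS1 of complex I, was 2.74-fold higher. The camera adjusted p was 7.1e-27, 7.1e-08 and 2.7e-06 in that order, and the adjusted p was 0.376 for each with an estimated correlation. Once the trend on GC content and length was removed, an alternative chosen after seeing the data, the respiratory chain list was no longer called, with a median of 0.045 and an adjusted p of 0.446. Ribosomal proteins then had a median of -0.23 and were still called.

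The remaining lists in MOLM-13 were not called. Translation factors had 17 of 36 members higher and 15 lower, with EIF5B, which joins the ribosomal subunits, 2.92-fold higher. Glycolytic enzymes had 2 of 17 higher and 8 lower, and the lactate dehydrogenase LDHA was 2.71-fold higher. Under library totals this list was called lower (median -0.57, camera adjusted p = 0.0422). Of 31 proteasome subunits, 15 were higher and 7 lower, with PSMD12 3.65-fold higher. Replication-dependent histones had 14 of 47 higher and 3 lower, with H2AC16 2.22-fold higher. With the trend on GC content and length removed, chosen after seeing the data, histones (median 1.04, camera adjusted p = 6.2e-06) and proteasome subunits (0.27, camera adjusted p = 0.0322) were called higher. Histone transcripts were short, with a median length of 436.5 bases, against 2853.5 for coding genes not called in MOLM-13. The histone call therefore rests on the short end of the fitted trend. Histones took a lower share of counts in MOLM-13 P-body libraries (0.0847% ± 0.0019) than in MOLM-13 cytosolic libraries (0.113% ± 0.0061, SD, n = 2). Over TMM, RLE and library totals, with no trend removed, the histone median ran from -0.14 to 0.31. P-body and mRNA decay proteins had 22 of 43 higher and 10 lower, with the decapping enzyme DCP2 2.64-fold higher. Of 40 genes of endoplasmic reticulum chaperones and translocon, 17 were higher and 18 lower, with SEC63 3.04-fold higher. Nuclear-retained long noncoding RNAs had 4 of 11 higher and 4 lower, with OIP5-AS1 2.62-fold higher. Of 5 small structured noncoding RNAs, 1 was higher and 1 lower, the latter being RN7SL1, 2.11-fold lower but called higher with the same trend removed (log2 change 0.16). Immediate-early and short-lived mRNAs had 10 of 45 higher and 11 lower, with JUND 2.79-fold lower. Iron handling and ferritinophagy genes had 9 of 23 higher and 8 lower. Monocytic and granulocytic markers, which mark the lineage of this line, had 7 of 25 higher and 11 lower, with the nuclear antigen MNDA 2.64-fold higher. Of 6 lymphoid markers, 0 were higher and 3 lower, with NKG7 1.75-fold lower, a call lost with the trend removed (log2 change -0.083, edgeR adjusted p = 0.287). With 4 tested members, 2 of them lower, erythroid and megakaryocytic markers were not tested as a list, and NFE2 was 1.52-fold lower. Adjusted over the list alone, the higher and lower counts were 17 and 17 for translation factors, 15 and 8 for proteasome subunits, 12 and 3 for histones, 23 and 10 for P-body and mRNA decay proteins, 10 and 10 for immediate-early mRNAs, 9 and 9 for iron handling genes, 7 and 13 for monocytic markers and 0 and 4 for lymphoid markers, and the same as over all genes for the other lists not called. The median was negative and both the mean and the camera direction positive for translation factors (-0.079) and endoplasmic reticulum genes (-0.11) in MOLM-13 and nuclear-retained noncoding RNAs in HEL (-0.0075). The median and camera direction were negative and the mean positive for endoplasmic reticulum genes in HEL (median -0.014) and, in MOLM-13, for nuclear-retained noncoding RNAs (-0.16) and immediate-early mRNAs (-0.0042). For histones in HEL the median (0.11) and mean were positive and the camera direction negative. Without MOLM-13 cytosol replicate 1, P-body and mRNA decay proteins (median 0.38) and monocytic and granulocytic markers (-0.22) were called.

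**Figure D1:**
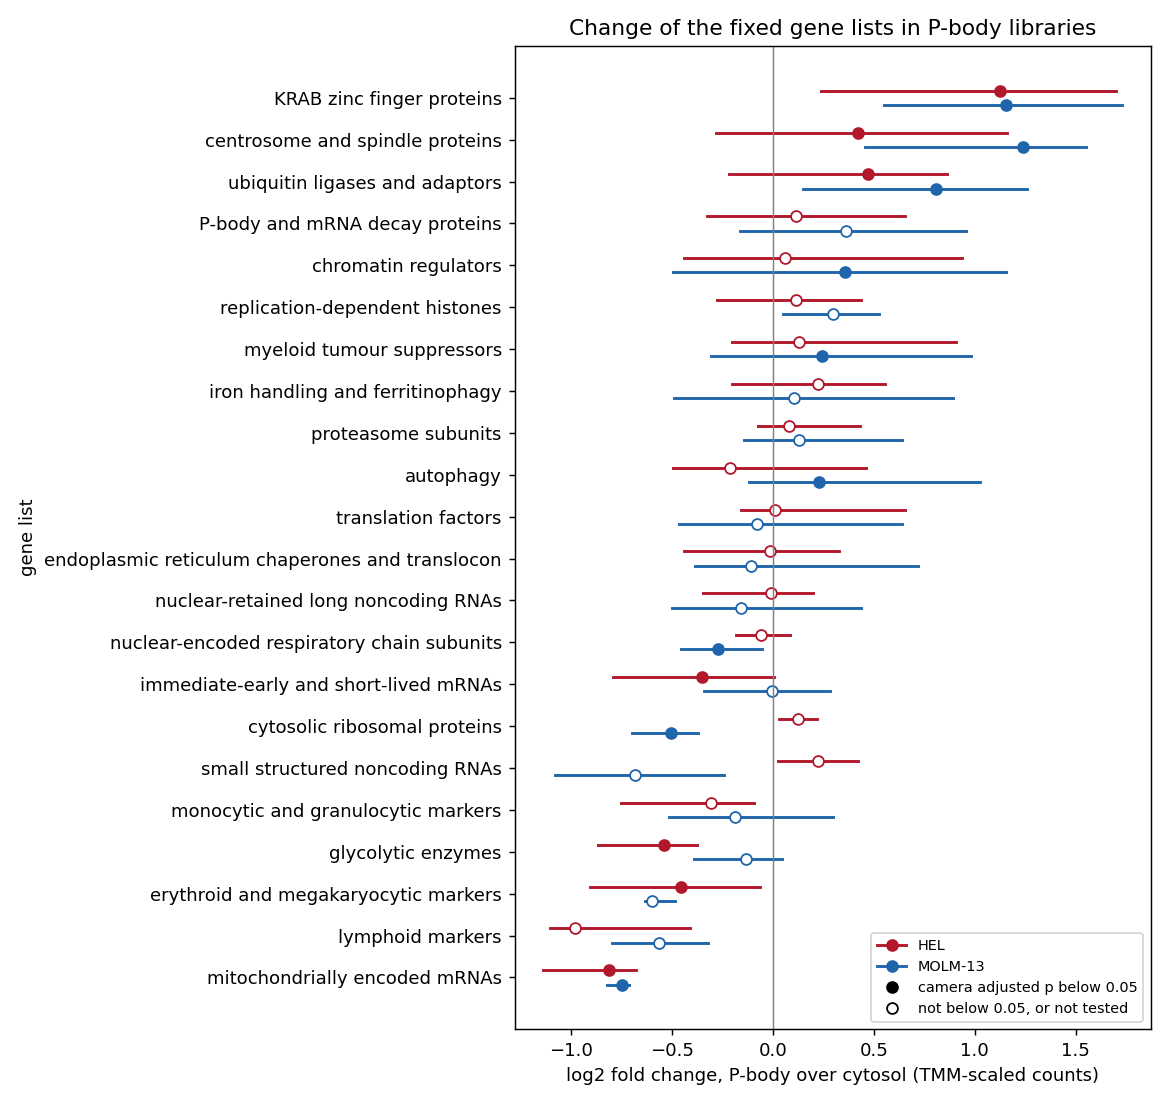
Median log2 fold change of each gene list between P-body and cytosolic libraries (points) with the quartiles over its tested members (lines), for HEL in red and MOLM-13 in blue. Filled points mark lists with a camera adjusted p below 0.05 under the preset correlation; KRAB zinc finger genes had medians of 1.13 in HEL and 1.15 in MOLM-13, and ribosomal protein genes had medians of 0.12, which turned negative under library totals, and -0.50.

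A set of 9 genes was followed in both lines whatever its result. NCOA4 (chromosome 10, 46005088 to 46030714, minus strand), the receptor that delivers ferritin to autophagy, was 1.59-fold higher in HEL P-bodies (log2 change 0.67 ± 0.075, SE, adjusted p = 2.63e-06) and 2.25-fold higher in MOLM-13 P-bodies (1.17 ± 0.068, adjusted p = 1.13e-13). TET2 (chromosome 4, 105145875 to 105279816, plus strand), which oxidises methylcytosine, was 4.27-fold higher in HEL and 3.96-fold higher in MOLM-13. The values given below with the trend on GC content and length removed come from an alternative chosen after seeing the data. The proto-oncogene MYC was 1.73-fold lower in HEL and 1.22-fold lower in MOLM-13, where the call was lost with that trend removed (log2 change -0.075, edgeR adjusted p = 0.327) and without MOLM-13 cytosol replicate 2 (-0.17, adjusted p = 0.0513). DDX6, the P-body helicase, had log2 changes of 0.18 and 0.10 that did not pass the test (adjusted p = 0.0646 and 0.294). Its call depended on the setting, as DDX6 was called higher in HEL under RLE (0.24), in DESeq2 (0.24), in the joint fit (0.26) and without HEL P-body replicate 2 (0.33), lower in MOLM-13 under library totals (-0.34), and lower in both lines with the trend removed (-0.46 and -0.60). LSM14A, a P-body scaffold protein (chromosome 19, 34172504 to 34229515, plus strand), was 1.43-fold lower in HEL, and its log2 change of -0.07 in MOLM-13 did not pass the test. LSM14A was called lower in MOLM-13 under library totals (-0.51), with CPM of at least 5 (-0.16), in the joint fit (-0.18), without MOLM-13 cytosol replicate 2 (-0.086) and with the trend removed (-0.74, edgeR adjusted p = 7.9e-13). The decapping scaffold EDC4 was 2.15-fold lower in HEL and 2.52-fold higher in MOLM-13, where its level was low (8.15 ± 3.57 against 3.18 ± 0.12 CPM, SD, n = 2) and the log2 change was 0.84 without MOLM-13 P-body replicate 2, in place of 1.33. ACTB was 1.41-fold lower in HEL and 1.35-fold lower in MOLM-13, and GAPDH 1.30-fold and 1.13-fold lower, the latter call being lost in DESeq2 (log2 change -0.16), without MOLM-13 P-body replicate 1 (-0.12) and without MOLM-13 cytosol replicate 2 (-0.02). With the trend removed the HEL call of ACTB was lost (-0.051, edgeR adjusted p = 0.349), and GAPDH was called higher in both lines (0.15 and 0.29). The nuclear RNA MALAT1 had a log2 change of -0.01 in HEL, which did not pass the test, and was 1.40-fold lower in MOLM-13. In HEL, MALAT1 was called lower under library totals (-0.33) and with the trend removed (-0.62).

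The P-body changes of both lines went together. Over 11984 genes tested in both, the log2 changes had a Pearson correlation of 0.71 and a Spearman correlation of 0.68 across genes, which are not independent replicates. In P-bodies of both lines 2933 genes were higher, against 1250 for independent lists of the same sizes, and 1783 were lower, against 990. In opposite directions, 105 genes were higher in HEL and lower in MOLM-13, and 290 were lower in HEL and higher in MOLM-13. The lines share no libraries. The Pearson correlation was 0.64 without HEL P-body replicate 1. In both lines the change followed transcript GC content (Spearman correlation -0.67 in HEL and -0.72 in MOLM-13, given below). Agreement with that trend removed was not computed, so a GC bias common to both preparations may contribute.

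The difference between lines was tested as an interaction over all 8 libraries. The genes with the lowest p-values that were relatively higher in MOLM-13 P-bodies were CENPE, a kinesin of the kinetochore, TPR, a nuclear pore protein, the Golgi proteins GOLGA4 and GOLGB1, and GARS1, a tRNA synthetase. CENPE was 1.83-fold lower in HEL P-bodies and 2.99-fold higher in MOLM-13 P-bodies (difference in log2 change 2.26 ± 0.088, SE, adjusted p = 8.0e-13), and TPR was 1.80-fold lower and 2.28-fold higher (difference 1.85, adjusted p = 4.7e-12). The corresponding genes relatively lower in MOLM-13 were RSBN1, NAP1L1, a histone chaperone, the receptor GPR85, YBX1, a cold-shock protein that binds mRNA, and PAG1, a membrane adaptor. RSBN1 was 3.43-fold higher in HEL P-bodies against 1.14-fold in MOLM-13 (difference -1.78, adjusted p = 2.2e-10), and its MOLM-13 log2 change turned to -0.25 with library totals and to -0.55 with the trend on GC content and length removed. The MOLM-13 call of RSBN1 was also lost in DESeq2 (0.20), in the joint fit (0.075), with CPM of at least 5 (0.097), without MOLM-13 P-body replicate 2 (0.17) and without MOLM-13 cytosol replicate 2 (0.14). YBX1 was 1.88-fold lower in MOLM-13 P-bodies, and its log2 change of 0.04 in HEL did not pass the test, while it was called at -0.28 under library totals and at 0.34 with that trend removed (difference -1.14, adjusted p = 8.4e-09). Of 17477 genes, 1600 were relatively higher and 2275 relatively lower in MOLM-13. This split depended on the scaling and on the libraries used. The higher and lower counts were 3441 and 1215 without HEL P-body replicate 1, 3053 and 915 without HEL cytosol replicate 1, and 2825 and 880 without HEL cytosol replicate 2. With each library in turn as the TMM reference the share of relatively higher genes among those called ran from 39.8% to 77.5%, against 41.3% here, and it was 51.7% with library totals and 52.9% with DESeq2. Called in the same direction under each of 10 scalings were 1485 of the 1600 and 1009 of the 2275 genes, among them the 10 genes named here.

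Among the gene lists, cytosolic ribosomal proteins differed most between lines in the camera test, with 77 of 78 members relatively lower in MOLM-13 and 0 relatively higher. The median difference in log2 change was -0.83 (camera adjusted p = 4.7e-50, and adjusted p = 0.400 with an estimated correlation), and it lay between -0.83 and -0.51 over the 10 scalings. RPL6 was 1.34-fold higher in HEL P-bodies, a call lost under library totals (log2 change 0.10), and lower in MOLM-13 P-bodies (log2 change -0.26). Nuclear-encoded respiratory chain subunits had 41 of 71 members relatively lower and 6 relatively higher (adjusted p = 4.1e-07, and 0.594 with an estimated correlation); without HEL cytosol replicate 2 the adjusted p was 0.0960. Centrosome and spindle genes had 26 of 59 members relatively higher in MOLM-13 and 4 relatively lower (adjusted p = 9.2e-10, and 0.450 with an estimated correlation). The median difference was negative and the camera direction positive for histones (-0.13), myeloid tumour suppressors (-0.11) and lymphoid markers (-0.38), none of them called.

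The shares of library counts are given per library for the same gene classes and are not scaled by TMM. Mitochondrially encoded mRNAs took 0.347% ± 0.013 of counts in HEL P-body libraries and 0.736% ± 0.064 in HEL cytosolic libraries (SD, n = 2), and 0.469% ± 0.0074 against 0.991% ± 0.094 in MOLM-13. Ribosomal protein genes took 2.00% ± 0.20 against 2.33% ± 0.070 in HEL, and 5.70% ± 0.17 against 10.7% ± 0.42 in MOLM-13. The lower share in HEL P-bodies runs opposite to the list's median log2 change of 0.12 under TMM, which was -0.20 under library totals. KRAB zinc finger genes took 0.684% ± 0.030 against 0.342% ± 0.015 in HEL, and 0.416% ± 0.0061 against 0.214% ± 0.0013 in MOLM-13. In each of these comparisons both P-body libraries lay on the same side of both cytosolic libraries, which chance alone gives with p = 0.333 in a two-sided exact permutation test of 2 against 2.

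**Figure D2:**
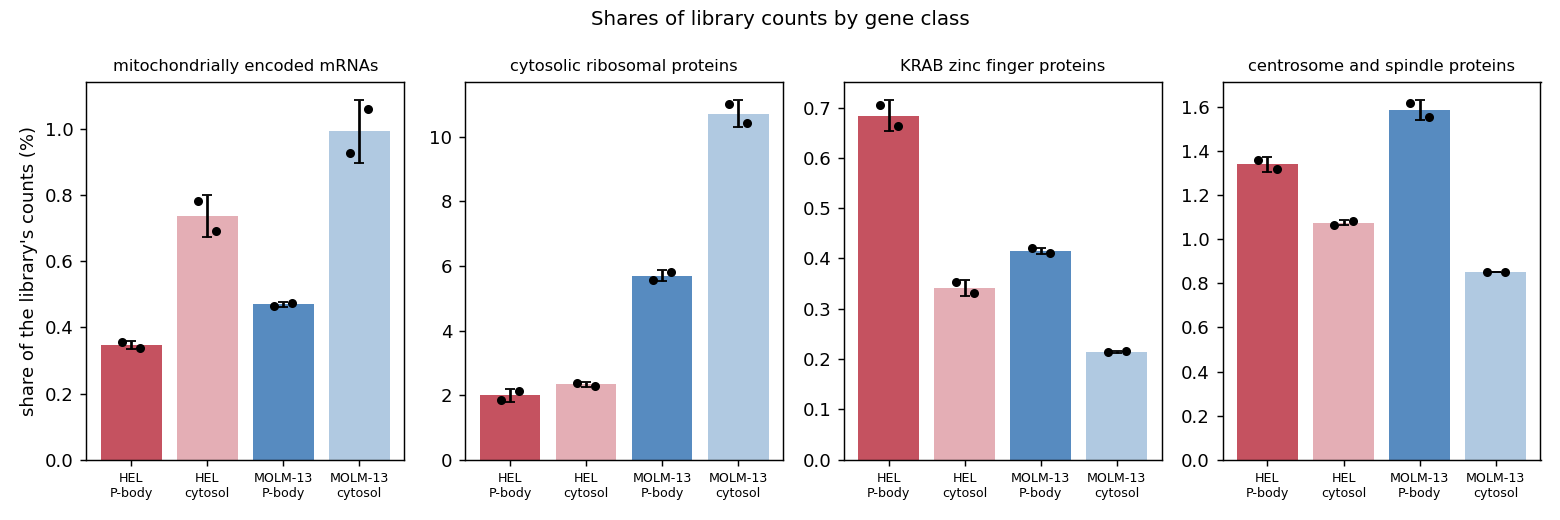
Share of each library's counts taken by 4 gene classes, in percent, with dots for libraries, bars for the mean of each group and lines for the SD of 2 libraries. Ribosomal protein genes took 10.7% of counts in MOLM-13 cytosolic libraries and 5.70% in MOLM-13 P-body libraries, and 2.33% and 2.00% in HEL.

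Genes higher in P-bodies had transcripts of low GC content. Across 11939 coding genes in HEL, the log2 change had a Spearman correlation of -0.67 with transcript GC content, and across 11224 coding genes in MOLM-13 it was -0.72, across genes that are not independent replicates. Median GC content was 41.5% for genes higher in HEL P-bodies, 50.4% for genes not called and 56.4% for genes lower, and 42.2%, 51.0% and 58.4% in MOLM-13. In the decile of HEL genes with the lowest GC content, 79.4% were higher and 2.17% lower in P-bodies, and in the decile with the highest GC content 1.26% were higher and 55.7% lower. The corresponding values in MOLM-13 were 80.4% and 3.03%, and 1.25% and 74.4%. The correlation with GC content of the coding sequence was -0.64 in HEL and -0.72 in MOLM-13, and with that of the 3′ UTR it was -0.58 and -0.63. Correlations with length were lower in size, at 0.14 and 0.23 for the transcript, 0.01 and 0.18 for the coding sequence, and 0.19 and 0.21 for the 3′ UTR. Given GC content, the partial Spearman correlation with transcript length was -0.095 in HEL and 0.013 in MOLM-13. The positive correlation with transcript length was therefore not seen in HEL, and was near 0 in MOLM-13, once GC content was held fixed.

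With the trend on GC content and length removed, chosen after seeing the data, further named genes moved by over 1.5 times and kept their call. In HEL the log2 changes were then 1.51 for ZNF92, 1.44 for CEP97, 1.28 for RN7SL1, 1.09 for PHF6, 1.07 for ZNF267, 1.06 for RSBN1, 1.05 for EIF1AX, 1.02 for ATG4C and TAX1BP1, 0.77 for SEC62, 0.63 for MDM2 and 0.41 for PSMC6. They were -1.74 for CENPE, -1.48 for TPR, -1.26 for SDHD, -1.07 for LSM14A, -0.80 for JUND, -0.79 for ALDOC, -0.69 for PIM1, -0.55 for EDC4, -0.54 for CD4, -0.41 for MYC, -0.38 for H2BC12 and -0.35 for SPI1. In MOLM-13 they were 2.35 for H2AC16, 1.37 for ZNF267, 1.22 for TAX1BP1, 1.14 for SMC3, 1.13 for PSMD12, 1.09 for ARID4A, 0.90 for LDHA, 0.88 for SEC63, 0.87 for CENPE, 0.80 for EIF5B and NDUFS1, 0.70 for MNDA, 0.67 for DCP2 and OIP5-AS1 and 0.53 for TPR. They were -1.15 for MALAT1, -0.52 for JUND, -0.31 for NFE2 and -0.10 for RPS2 and ACTB. Library totals moved NCOA4 to 0.34 in HEL and 0.73 in MOLM-13, and TPR to 0.75 and H2AC16 to 0.71 in MOLM-13.

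**Figure D3:**
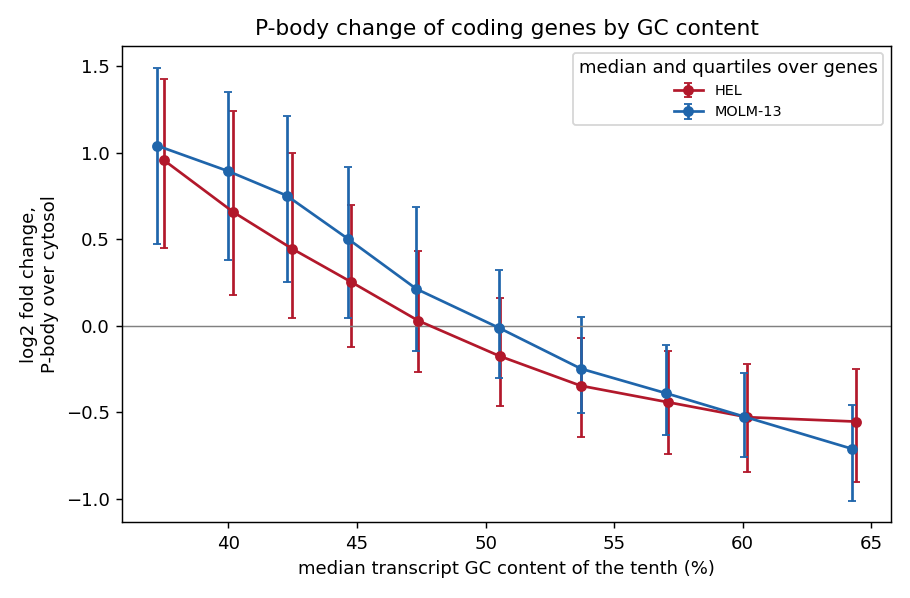
Median log2 fold change between P-body and cytosolic libraries (vertical axis, with quartiles as bars) of coding genes in deciles of transcript GC content (horizontal axis, percent), for HEL in red and MOLM-13 in blue, drawn slightly side by side. The median ran from 0.96 in the lowest decile to -0.55 in the highest in HEL and from 1.04 to -0.71 in MOLM-13.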

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

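The tests of scaling on ribosomal protein genes, of the lists between lines and of each TMM reference library were chosen only after the results had been seen.

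Genes were marked here because the test of the difference between lines passed, with the MOLM-13 minus HEL difference in log2 P-body change as the value. Relatively higher in MOLM-13 were CENPE (2.26), EDC4 (2.24), TPR (1.85), GOLGA4 (1.55), GOLGB1 (1.36), GARS1 (1.24), LDHA (1.19), UPF1 (0.97, a call lost in DESeq2), NDUFS1 (0.87), BORA (0.79), SMC3 (0.78), H2BC12 (0.78), ALDOC (0.77), CNTRL (0.66), PSMD12 (0.62), PSMC6 (0.57), UBLCP1 (0.52) and SEC63 (0.49). In the joint fit the log2 changes in HEL and MOLM-13 were -0.93 and -0.15 for H2BC12, 0.13 and 1.32 for LDHA, and -1.19 and -0.41 for ALDOC. PIM1 (0.58), MT-ND4 (0.41), MDM2 (0.33), MYC (0.32), NCOA4 (0.32) and LSM14A (0.25) were also relatively higher, but each lost the call in some fits that left out a library. For NCOA4 the value ran from 0.22 to 0.72 in these fits. Over the 10 scalings, MDM2, MYC, NCOA4 and LSM14A were called in this direction in 8, and PIM1 and MT-ND4 in all 10.

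Relatively lower in MOLM-13 were GPR85 (-2.70), RN7SL1 (-1.89), RSBN1 (-1.78), PAG1 (-1.64), BBLN (-1.48), ZNF787 (-1.48), SNHG14 (-1.23), NAP1L1 (-1.18), YBX1 (-1.14), KLHL28 (-1.07), TNRC6A (-0.96), CEP97 (-0.89), SEC62 (-0.89), RPL6 (-0.88), RPS2 (-0.72), MALAT1 (-0.67) and EIF1AX (-0.66). With a library left out, the highest values were -0.71 for KLHL28, -0.64 for TNRC6A, -0.51 for CEP97 and -0.53 for SEC62. They were -0.57 for RPL6, -0.42 for RPS2, -0.30 for MALAT1 and -0.32 for EIF1AX. ZNF787 was no longer called without HEL P-body replicate 2 (-0.61), HEL cytosol replicate 1 (-1.03) or MOLM-13 P-body replicate 1 (-1.35). DCP2 (-0.40), ASH1L (-0.37) and MT-CO2 (-0.30) lost the call with each MOLM-13 library as TMM reference, and with a library left out in 3, 5 and 6 of 8 fits, in that order. The values in these fits ran from -0.41 to -0.038, from -0.46 to 0.024 and from -0.34 to 0.066. Over the 10 scalings the call was kept in 6 for DCP2 and for ASH1L, and in only 3 for MT-CO2. LIMCH1 (-3.93), RGS17 (-3.91), ZNF141 (-4.53) and NKG7 (-4.99) rest on few counts in the line where they were not tested, so the values are no bound. LIMCH1, ZNF141 and NKG7 also lost the call in some fits that left out a library. In these fits LIMCH1 ran from -4.40 to -3.09, RGS17 from -4.26 to -3.51, ZNF141 from -8.06 to 0.35 and NKG7 from -5.58 to -3.51. LIMCH1 had 3, 5, 2 and 6 counts in the MOLM-13 libraries and RGS17 10, 6, 11 and 8, in the order of both P-body and both cytosolic libraries. ZNF141 had 2, 0, 4 and 0 in MOLM-13, and NKG7 had 4, 1, 0 and 0 in HEL.

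Among lists, the median differences were -0.83 for cytosolic ribosomal proteins, -0.43 for nuclear-encoded respiratory chain subunits, -0.20 for translation factors, 0.25 for centrosome and spindle proteins, 0.24 for glycolytic enzymes, 0.20 for autophagy and 0.15 for ubiquitin ligases and adaptors. None of these list calls held in camera with an estimated correlation, where the adjusted p was 0.400 for ribosomal proteins, translation factors and autophagy, 0.594 for respiratory chain subunits, 0.450 for centrosome and spindle proteins, and 0.762 for glycolytic enzymes and ubiquitin ligases. Over the 10 scalings these medians ran from -0.83 to -0.51 for ribosomal proteins, -0.43 to -0.11 for respiratory chain subunits, -0.21 to 0.12 for translation factors, 0.25 to 0.57 for centrosome and spindle proteins, 0.23 to 0.56 for glycolytic enzymes, 0.19 to 0.51 for autophagy and 0.15 to 0.47 for ubiquitin ligases. The translation factor call was lost with each MOLM-13 library as TMM reference, and without HEL P-body replicate 1 (0.12), HEL cytosol replicate 1 (0.067) or HEL cytosol replicate 2 (0.10). The respiratory chain call was lost without HEL cytosol replicate 2 (-0.080). Calls were gained by immediate-early mRNAs with no low-count filter (0.14) and without HEL P-body replicate 2 (0.27) or HEL cytosol replicate 1 (0.36), and by tumour suppressors (0.21 and 0.22) and chromatin regulators (0.24 and 0.28) without HEL P-body replicate 1 or HEL cytosol replicate 1. Proteasome subunits were called without HEL P-body replicate 1 (0.23) or HEL cytosol replicate 2 (0.20), and mitochondrially encoded mRNAs without the latter (0.17). Symbols that stand on several rows, which were left out of the tests, took a greater share of counts in both HEL P-body libraries (at least 0.0250%) than in both HEL cytosolic libraries.

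The P-body over cytosol change of ribosomal protein mRNAs, which was lower in MOLM-13 than in HEL, was weighed against technical explanations. Their share of P-body counts itself was greater in MOLM-13 (5.70%) than in HEL (2.00%). The difference between the list's medians in the fits of each line was -0.62 at its nearest to 0 over TMM, RLE and library totals. None of these scalings removed it. They shift the genes of a line about alike, by amounts known when the test was set, so scaling in general is not excluded. In the joint fit the median difference was -0.51 at its nearest to 0 over 10 scalings. The trend on GC content and length of all other genes fell short as a cause, as the list's median distance from it differed by -0.51 between lines. A difference between the lines and a difference between their preparations both stay open and untested, since they are the same split in these libraries.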

How the results depend on the processing

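The tests with GC and length offsets and with each TMM reference library were chosen only after the results had been seen. Of 3908 alternative values for named genes 3625 kept their side of the threshold, 123 of which changed sign with no call in either fit, 154 were no longer called, 93 became called, and 36 changed sign with a call in at least one fit. Calls need replicate spread to be estimated from 2 libraries a group, and a fit without a library assumes that the lone library varies like the other group. The cause was not tested unless stated.

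Library totals gave 6761 lower genes in HEL, and 2903 higher and 7154 lower in MOLM-13, by the shift in scaling. A tested minimum change of 2-fold left 1097 and 185 genes in HEL and 1364 and 141 in MOLM-13, by its construction. DESeq2 gave 2623 lower genes in MOLM-13 and 1466 genes relatively lower in MOLM-13, with 1093 and 6099 genes without an adjusted p. GC and length offsets left 2519 lower genes in MOLM-13. Of the 8067 calls in HEL, 7636 were shared with RLE, and of the 8573 in MOLM-13, 8517. Over all genes, same-numbered libraries showed no shared deviation (correlation of deviations -0.068 in HEL and -0.010 in MOLM-13). The 5 genes with the greatest falls in HEL nevertheless had more counts in replicate 2 of both fractions, by more than the totals differ. For ADRA2A these were 51 and 114 in P-body replicates 1 and 2, and 303 and 620 in cytosol replicates 1 and 2. A pairing of the HEL replicates is therefore not excluded. With the replicate number as a block, HEL had 4024 higher and 3972 lower genes, MOLM-13 4574 and 4015, and the difference between lines 1547 and 2166; the block called the monocytic list in MOLM-13 (median -0.19, adjusted p = 0.0329), called the differences of ITGB5 and RNPEPL1 and ended that of MYC, and changed no other call of a list or named gene.

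For the difference between lines, the choice of reference library set the split. With MOLM-13 P-body replicate 1 or 2 as the TMM reference 3384 and 3472 genes were relatively higher in MOLM-13 and 1038 and 1009 lower, and with MOLM-13 cytosol replicate 1 or 2 the numbers were 3034 and 3151, and 1193 and 1138. Leaving out each library gave 1198 to 3441 higher and 880 to 2054 lower. Without HEL P-body replicate 1 there were 3441 and 1215, without HEL cytosol replicate 1 3053 and 915, and without HEL cytosol replicate 2 2825 and 880.

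Of the called lists, 3 higher and 4 lower in HEL and 6 higher and 3 lower in MOLM-13, 0 remained in each with an estimated correlation. That test had 2 residual degrees of freedom in each line. KRAB zinc finger genes lost the call in MOLM-13 at an estimated correlation of -0.0053, so correlation between members does not account for that loss. fry, which does not compare a list with other genes, called 10 higher lists in HEL, and 13 higher and 6 lower in MOLM-13. Library totals and the filter of CPM of at least 5 each left 3 higher lists in MOLM-13, and GC and length offsets left 2 lower lists in HEL. Leaving out a library gave 3 to 6 higher lists in HEL. The correlation between lines was 0.68 by Spearman, 0.78 with CPM of at least 5, and 0.64 to 0.72 with a library left out. The GC correlation was -0.70 in HEL and -0.76 in MOLM-13 with CPM of at least 5, and -0.71 in MOLM-13 with the longest transcript.

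Sign changes are given for values called in at least one of both fits, with the direction of a list taken from its test. Under library totals they were, in log2 change, LDHA -0.27, GOLGA4 -0.011, GOLGB1 -0.20 and YBX1 -0.28 in HEL, and DDX6 -0.34, RSBN1 -0.25 and NAP1L1 -0.094 in MOLM-13. Under GC and length offsets they were BBLN 0.084, RPS2 0.23, NDUFS1 -0.14, LDHA -0.33, DDX6 -0.46, GAPDH 0.15, GOLGA4 -0.38, GOLGB1 -0.35 and the ubiquitin list -0.012 in HEL, and ALDOC 0.058, H2BC12 1.06, RN7SL1 0.16, SPI1 0.33, DDX6 -0.60, GAPDH 0.29, RSBN1 -0.55 and NAP1L1 -0.31 in MOLM-13. Under library totals the medians of the P-body and mRNA decay list (-0.21 in HEL and -0.077 in MOLM-13), proteasome subunits (-0.24 and -0.31) and, in HEL, tumour suppressors (-0.20) also turned negative, among others, with no call in either fit. fry gave the opposite direction to camera for the endoplasmic reticulum list in HEL (median -0.014) and for nuclear noncoding RNAs (-0.16) and immediate-early mRNAs (-0.0042) in MOLM-13.

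Differences between lines that changed sign with another TMM reference and were called in at least one of both fits were EIF5B (0.30, 0.31, 0.25 and 0.26 with the MOLM-13 libraries) and MT-CO2 (0.00077 and 0.012 with the MOLM-13 P-body libraries). Over the 10 scalings, differences not called here also turned positive, among others those of ACTB (up to 0.18), PHF6 (0.16), ARID4A (0.21), DDX6 (0.038) and TET2 (0.012). The medians of 13 lists turned positive too, among them translation factors (up to 0.12), which were called here, and KRAB zinc finger proteins (0.14), which were not. With a library left out the ranges were -0.035 to 0.31 for EIF5B, -0.34 to 0.066 for MT-CO2, -0.46 to 0.024 for ASH1L, -0.20 to 0.25 for ACTB and -8.06 to 0.35 for ZNF141. For lists they were -0.23 to 0.12 for translation factors, -0.12 to 0.23 for proteasome subunits, -0.11 to 0.28 for chromatin regulators and -0.28 to 0.20 for mitochondrially encoded mRNAs.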

Other observations

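The test of scaling on mitochondrially encoded mRNAs and the removal of the trend on GC content and length were chosen only after the results had been seen.

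Noncoding genes and pseudogenes moved apart from coding genes in MOLM-13. Of 2592 tested, 315 were higher and 754 lower in MOLM-13 P-bodies, with a median log2 change of -0.35, against 0.047 for 11224 coding genes. In HEL 319 of 2560 were higher and 319 lower, with a median of -0.058, against -0.059 for coding genes. This difference was not tested.

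LSM14A, which encodes a P-body protein, was among the genes with the most counts, in rank 6 and 4 in the HEL P-body libraries and rank 2 in both HEL cytosolic libraries, and in rank 26 and 15 in the MOLM-13 P-body and cytosolic libraries. It took 0.214% of counts in HEL P-body libraries and 0.383% in cytosolic ones. The counts cannot tell reads of the native LSM14A gene from reads of any introduced copy, and how the P-bodies were isolated is not given. The gene with the most counts was NCL, encoding nucleolin, in each P-body library, a gene chosen after its values were seen. It was ACTB in the HEL cytosolic libraries and MT-RNR2, a mitochondrial ribosomal RNA, in the MOLM-13 cytosolic libraries. Ribosomal protein genes took 2.33% of counts in HEL cytosolic libraries and 10.7% in MOLM-13 cytosolic libraries.

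That mRNAs of low GC content are higher in P-bodies may reflect a property of the transcripts or of the libraries. Transcript length argues against itself as the cause, since the partial Spearman correlation with GC content given length was -0.67 in HEL and -0.70 in MOLM-13. Fragment-level GC bias would be at least as visible in a long 3′ UTR as in a short coding sequence. Among coding genes whose 3′ UTR is longer than the coding sequence (4526 in HEL and 4213 in MOLM-13), the partial correlation with coding GC minus that with 3′ UTR GC was -0.037 in HEL and -0.17 in MOLM-13, where a bound of -0.1 in both lines had been set beforehand, so this bias and a preference of P-bodies cannot be told apart. With the trend on GC content and length removed, 61.4% of calls in HEL and 61.0% in MOLM-13 were still made, of which 371 of 4956 and 486 of 5227 had the opposite sign.

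Mitochondrially encoded mRNAs were lower in P-body libraries although their GC content predicts otherwise. Their median distance from the trend on GC content and length of all other genes was -1.27 in HEL and -0.88 in MOLM-13, which argues against that trend. Over TMM, RLE and library totals the median change was -0.74 in the line nearest to 0, so none of these scalings removed it. Their shifts were known when this test was set, so scaling in general is not excluded. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2, chosen after their values were seen, had log2 changes of -0.05 and -0.09 in HEL under TMM, which did not pass the test, and of -0.86 and -0.82 in MOLM-13. Their share of counts, not scaled by TMM, was lower in P-body libraries of both lines. It was 0.171% ± 0.0048 against 0.228% ± 0.017 in HEL cytosol (SD, n = 2), and 0.372% against 0.889% in MOLM-13. The HEL result for these RNAs therefore depends on the scaling. No biological explanation was tested.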
